A study of Mus musculus and synthetic construct with 21 samples.

How the data were processed

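The series measured enhancer activity and PPARγ binding of designed DNA elements in 3T3-L1 cells, a mouse line that differentiates from pre-adipocytes to adipocytes. Per the labels' protocols, confluent cells were induced with 1 µM dexamethasone, 1.7 µM insulin and 0.5 mM IBMX. In a massively parallel reporter assay (MPRA), each element drives a transcript that carries a barcode, and RNA barcodes are set against the same barcodes in the plasmid library. RNA and chromatin were taken 16 h after transfection. There were 7 pools of elements, each with 1 RNA and 1 plasmid library. Pools 1 and 2 also had 1 PPARγ ChIP and 1 input (WCE) library each. No library had a replicate, so each test below ran over sites, elements or barcodes within libraries, and none of the p-values covers variation between cultures.

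The deposited MPRA values were raw read counts, per barcode for pools 1 to 4 and summed over all barcodes of an element for pools 5 to 7, per the file headers and the series' design text. The design text places pool 4 among the summed pools, but its table held 13 barcode columns per element and was handled per barcode. Per the submitters' processing notes, the build was mm9, and Bowtie2 2.1.0 and BWA 0.7.12 were used. The deposited pool 1 ChIP table held raw read counts for 1992 elements, with no input count under 101. The deposited barcode maps of pools 5 to 7 linked a median of 134, 144 and 148 barcodes to each element.

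The column headed IP in the pool 2 ChIP table was not used as ChIP counts. Each of its 595 values equalled the input count of its row times the median raw RNA over plasmid ratio of a bound5 element of pool 2, within a rounding tolerance of 0.5. The match held after the second site numbers, which ran in 1 fixed order in all 25 blocks of the table, were paired by position with the 25 numbers sorted as text and then exchanged with the first numbers. This formula was found by a search, after the data were seen, over 112 combinations of count minimum, pseudocount, scaling and treatment of zeros, besides 24 combinations of pairing, series and ratio form. The best combination, barcodes with at least 50 plasmid counts and no pseudocount, recovered 595 values, the next 593, and the form with no minimum and no pseudocount 584. Whether the values arose at deposit or in the copy used here is unknown. For the pool 1 table, a bound was computed that needs no pairing rule, the most values that any 1-to-1 pairing of its elements with pool 1 ratios could recover by this formula. It was 561 of 1992, against 595 of 595 for pool 2. With the ratios multiplied by the best of 20001 scale factors it was 1331 of 1992, against 593 of 595, and the pool 1 table was kept. With the medians aligned it did not separate the tables (1254 of 1992 and 359 of 595). This bound was added after the data were seen. With each pool 1 element paired by its own name, 1 of 1992 values was recovered, by the median ratio and also by the ratio of sums. Further formulas were not tried on pool 1. Pool 2 binding was planned and is not analysed here.

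Activity was the log2 ratio of RNA to plasmid counts, each with a pseudocount of 1 and scaled to its library total. In pools 1 to 4 it was the median over barcodes with at least 20 plasmid counts, and in pools 5 to 7 it came from summed counts of elements with at least 50 plasmid counts. Binding in pool 1 was the log2 ratio of ChIP to input counts, for elements with at least 20 input counts. Elements with 0 RNA counts entered through the pseudocount. Activity is relative to the library totals of a pool, and levels were not compared between pools, although sites and motif names measured in more than 1 pool were correlated across pools. Coordinates are of mm9, counted from 1, and span the 16-base sequence in each element's name. No annotation of that build was used, so sites were not assigned to genes, and the planned lists of adipocyte genes could not be applied. Affinity was approximated by the number of mismatches to a 13-base DR1 consensus, counted as negative so that a higher score means a closer match.

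Differences at the same site were tested by 2-sided sign flips, enumerated exactly below 17 differences and otherwise with 100000 permutations. The flips ran over sites in pools 1 to 4, over altered instances in pool 5, over slots in pool 6 (or sites, where stated) and over arrays or motif pairs in pool 7. Instances or slots of a site share its wt element and are not independent. Differences between sets of elements were tested by 100000 permutations of labels. Shares of variance used 2000 permutations. The smallest p-values these can give are 1e-05 for 100000 permutations and 0.0005 for 2000. Single sites of pools 1, 3 and 4 were tested over barcodes by permuting native and altered barcodes. That test used barcode means, while the effects printed are differences of barcode medians. Arrays of pool 7 were taken as units although they share 3 backgrounds, each measured as 1 element, so a test over backgrounds could not reach the threshold. Correlations were computed across elements, which are not replicates. Benjamini-Hochberg adjustment was made within each family, and calls used an adjusted p under 0.05. The named sites were the 10 with the largest effect in each direction among those called over barcodes, or by size alone in pools 5 to 7, which had no barcode values.

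Some steps departed from the plan made before the data were examined. Pool 7 lacked the elements for the planned interaction, and mixed arrays were compared with the mean of their 2 single-motif arrays. The planned test of motifs replaced in pool 6 was reduced to a description after its values had been seen. Tests per site in pool 6, the grouping of motif names into families, the grouping of pool 7 pairs by motif and by background, the relation between altering and inserting a motif, and the agreement of the same sites across pools were added after the data were seen. Families of motif names were assembled from general knowledge of transcription factors.

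The procedures were tested on simulated data. For the barcode test of pool 1 over 750 sites, 96% of sites changed by 2 on the log2 scale were called, 56% at 1, 67.3% at -1 and 20% at 0.5, with 4 of 544 unchanged sites called. The sign-flip test over 25 sites gave an unadjusted p under 0.05 in 14 of 200 simulated sets without a change. The differences in those sets were drawn independently and given random signs, which is what the test assumes. That rate could therefore not show how the test behaves with skewed or dependent differences. In a simulation of pool 6 over 39 motifs, all 5 motifs raised by 0.5 and all 5 lowered by 0.5 were called, and 0 of 29 unchanged ones. That simulation drew slots independently and raised as many motifs as it lowered. It could therefore not test the sharing of sites by slots, or shifts of the slot mean. Alternatives covered the pseudocount, the count minimum, the scaling, the summary over barcodes, random subsets of the barcodes and the average over sites. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.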

Results

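Enhancer activity was measured for 7 pools of elements in differentiating 3T3-L1 cells, and PPARγ binding to the plasmids was measured for pool 1. PPARγ is the nuclear receptor that drives adipocyte differentiation, and it binds as a dimer with RXR to DR1 motifs. RNA libraries held between 9806531 counts (pool 7) and 37267216 counts (pool 3), and plasmid libraries between 10179019 counts (pool 7) and 56246463 counts (pool 3). The pool 1 ChIP and input libraries held 1987761 and 1381624 counts. The median plasmid count per element was 11834 in pool 1, 32345 in pool 2, 4934.5 in pool 3, 17927 in pool 4, 4972 in pool 5, 5447 in pool 6 and 3223 in pool 7. Each library was made once, so spreads below are over sites or elements.

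Pools 1 and 3 addressed how the PPARγ motif and its surroundings set activity. Their names give 2 site classes, w and c, each with a native form (t) and a form read here as carrying an altered motif (d). The names do not spell out these codes. In pool 1, altering the motif lowered activity at w sites and had little effect at c sites. Native w elements were more active than altered ones by 0.66 ± 0.79 (SD, n = 749 sites; higher at 623), against 0.09 ± 0.42 at c sites (n = 750; higher at 443). Mean activity was 0.35 in native and -0.30 in altered w elements, against -0.52 and -0.60 in native and altered c elements. Native c elements thus already stood below altered w elements. The alteration effect was 0.57 ± 0.86 larger at the w site than at the c site of the same number (n = 749). Each pair of w and c elements in pool 1 shared its 16-base motif sequence (750 of 750), yet native w elements exceeded native c elements by 0.87 ± 1.05. With the motif altered, w elements still exceeded c elements by 0.30 ± 0.69 (n = 750). These 5 contrasts had p = 1e-05, the smallest the permutations can give, and adjusted p = 1e-05.

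Pool 3 held 1500 other sites per class, whose w and c elements share no motif sequence by number. Native exceeded altered elements by 0.60 ± 1.37 at w sites (n = 1498) and by 0.18 ± 1.24 at c sites (n = 1497). The effect was 0.42 larger at w sites, native w elements exceeded native c elements by 0.73, and altered w elements exceeded altered c elements by 0.31. All 5 contrasts again had permutation p = 1e-05, the smallest possible. The c-site effect was 0.051, with permutation adjusted p = 0.0704, when barcode counts were summed before taking the ratio.

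PPARγ binding to the plasmids of pool 1 depended on the motif in both classes. Native w elements were bound more than altered ones by 0.51 ± 0.86 (n = 541 sites; higher at 402), and native c elements by 0.29 ± 0.82 (n = 404; higher at 247). The difference between these effects was 0.19 ± 0.99 (n = 293; p = 0.00098, adjusted p = 0.00122). Native w elements were bound more than native c elements with the same motif sequence by 0.29 ± 1.00 (n = 339). The other 3 of these contrasts had p = 1e-05, the smallest the permutations can give. For altered elements the difference between classes was 0.11 ± 0.94 (n = 317; p = 0.0334, adjusted p = 0.0334), and by the median over sites it was 0.090 with adjusted p = 0.203.

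**Figure D1:**
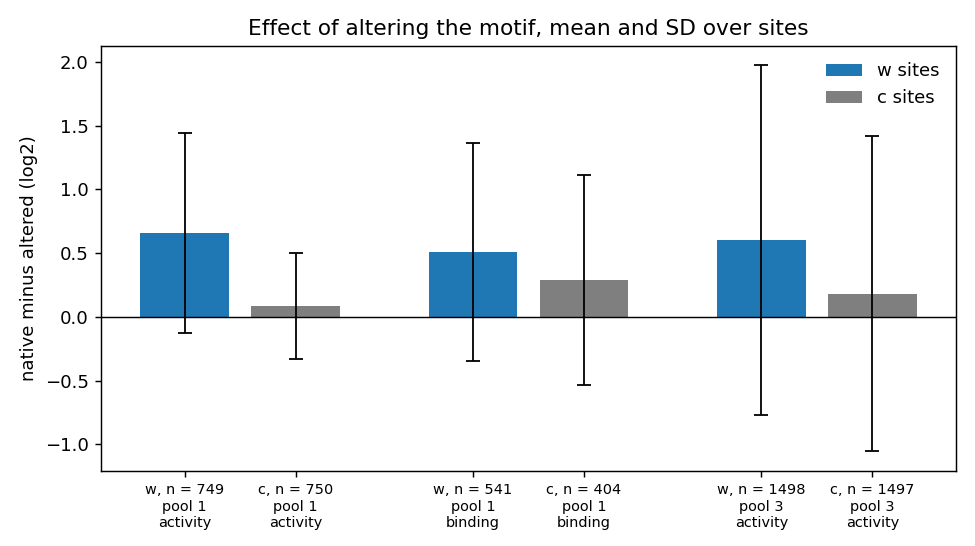
Native minus altered log2 activity or binding at w sites (blue) and c sites (grey) of pools 1 and 3, as means with SD over sites. The w bars for activity stand at 0.66 and 0.60 and the c bars at 0.09 and 0.18, while the binding bars stand at 0.51 and 0.29.

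Single sites were tested over their barcodes. In pool 1, 237 of 743 w sites were more active in the native form and 4 less active, against 10 and 2 of 749 c sites. In pool 3 the counts were 262 and 17 of 1445 w sites, and 9 and 0 of 1433 c sites, where 100 and 32 had an unadjusted p under 0.05. The largest pool 1 effect was 3.82 at w site 548 (chromosome 11, 90067250 to 90067265), where native activity was 3.51 and altered activity -0.31 (n = 9 and 9 barcodes, exact permutation p = 4.11e-05, the smallest possible, adjusted p = 0.000764). Sites 100 (chromosome 19, 3.38), 39 (chromosome 1, 3.21), 660 (chromosome 1, 3.06) and 142 (chromosome 3, 2.94) followed, and the remaining 5 of the 10 ranged from 2.79 to 2.93. The 4 w sites of pool 1 with lower native activity were 509 (-1.41, chromosome 9), 485 (-1.29, chromosome 7), 600 (-1.24, chromosome 4) and 292 (-1.01, chromosome 16), of which 485 and 600 did not pass with 5 times the count minimum. Among c sites, number 142 (chromosome 1) had the largest effect, 2.23, and number 664 (chromosome 14) the lowest, -1.92, which did not pass with either other count minimum. In pool 3, w site 1336 (chromosome 14) led with 7.17, from 12 native and 6 altered barcodes (permutation p = 0.000862, adjusted p = 0.00662), followed by site 1092 (chromosome 11, 5.24) and site 912 (chromosome 5, 4.94). The lowest was site 1098 (chromosome 6), at -3.98. The largest c-site effect of pool 3 was 4.05 at site 1401 (chromosome 16).

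Binding and activity were related only weakly across the native elements of pool 1, and no relation was detected across altered ones. For native w elements rho was 0.214 (p = 1e-05, the smallest possible, adjusted p = 3.5e-05) and r was 0.125 (p = 0.00272; 0.140 without the 2 farthest elements; n = 567). For native c elements rho was 0.202 (p = 4e-05, adjusted p = 5.6e-05) and r was 0.187 (p = 0.00011; 0.199 without the 2 farthest; n = 439). Altered w elements had rho 0.00812 (p = 0.845, adjusted p = 0.845) and r 0.0398 (p = 0.343; 0.0532 without the 2 farthest; n = 566). Altered c elements had rho 0.0567 (p = 0.249, adjusted p = 0.29) and r 0.0452 (p = 0.356; 0.0523 without the 2 farthest; n = 420). The alteration effects on binding and activity correlated across w sites (rho = 0.181, permutation p = 3e-05, adjusted p = 5.6e-05, n = 541). There r was 0.110 (permutation p = 0.0108), and 0.126 without the 2 farthest. Across c sites rho was 0.205 (permutation p = 4e-05, adjusted p = 5.6e-05, n = 404). There r was 0.178 (permutation p = 0.00036), and 0.170 without the 2 farthest. These are correlations across elements or sites, which are not replicates, in a family of 7.

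The sequence of the motif was related to native binding, and its relations with native activity were smaller or not detected. Where w and c elements shared a motif sequence, their native binding correlated (r = 0.315, p = 1e-05, the smallest possible; rho = 0.286, p = 1e-05, adjusted p = 3e-05; r = 0.325 without the 2 farthest; n = 339). Their native activity did not (r = 0.00361, p = 0.921; rho = -0.00544, p = 0.881, adjusted p = 0.881; r = 0.0110 without the 2 farthest; n = 749). Fewer mismatches to the DR1 consensus went with higher native binding at w elements (rho = 0.270, adjusted p = 3.33e-05; r = 0.254, p = 1e-05; 0.256 without the 2 farthest) and at c elements (rho = 0.268, adjusted p = 3.33e-05; r = 0.287, p = 1e-05; 0.292 without the 2 farthest). With native activity, rho was 0.0657 for w elements (p = 0.0714, adjusted p = 0.143) and 0.158 for c elements (p = 1e-05, adjusted p = 3.33e-05) in pool 1, and 0.0951 (p = 0.00028, adjusted p = 0.0007) and 0.0297 (p = 0.254, adjusted p = 0.318) in pool 3. The corresponding r values were 0.0400 (permutation p = 0.273), 0.134 (p = 0.00025), 0.0631 (p = 0.0146) and 0.0364 (p = 0.16), and without the 2 farthest elements 0.0422, 0.132, 0.0635 and 0.0379. The families held 6 and 10 relations across elements, which are not replicates. Whether binding and activity relations differed from each other was not tested.

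Pool 2 exchanged motifs between 25 sites, which separates differences between these motifs from differences between the surrounding sites. Each of the 25 sites carried the motifs of all 25 numbers, in series named bound0 and bound5. The surrounding site, read here as the first number in the name, accounted for most of the variance in activity. Read the other way, the numbers would exchange their shares. The second number compares 25 native motifs with each other, so its share does not measure the loss of a motif. The first number took 83.7% of the variance in bound0 and 70.8% in bound5. The second number took 6.00% and 14.4%, and 10.3% and 14.8% remained (p = 0.0005 for each share of a number, the smallest the permutations can give; n = 625 elements per series). Elements named mut were less active than native ones by -1.44 ± 1.06 (permutation adjusted p = 6e-05), dr1 by -0.99 ± 0.68 and ctrl by -2.05 ± 1.45 (adjusted p = 3e-05 for both). Elements named ctrl5 differed by -0.49 ± 0.76 (permutation adjusted p = 0.00284), and by -0.33 in the first of 2 random subsets of the barcodes (adjusted p = 0.0534). The mean of the 24 foreign motifs differed from the native motif by -0.23 ± 0.51 in bound0 (permutation p = 0.0307) and by -0.48 ± 0.60 in bound5 (p = 0.0006, adjusted p = 0.0009). The bound0 difference did not pass by the median over sites (-0.21, permutation adjusted p = 0.0962) or in the first subset (-0.19, adjusted p = 0.0652). All used n = 25 sites. These sites were not typical of w sites. Their altered minus native difference was lower in pool 1 than in pool 2, by -0.21 ± 0.42 on average. Over 749 w sites of pool 1, native exceeded altered elements by only 0.66. Sites 39, 100, 126, 142 and 199 were among the 10 largest called effects there, while site 509 had the lowest. The effects and shares above were not shown for w sites in general. The values headed IP in the pool 2 table could be rebuilt from the input and the reporter counts in 595 of 595 cases, so binding in pool 2 is not analysed here.

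Pool 4 scanned the same 25 sites with altered windows. These sites are not typical of w sites, so the effects below apply to them and not to the class. Altering the motif (mut) changed activity by -1.36 ± 1.02 and the ctrl form differed by -1.66 ± 1.32 (n = 25; p = 1e-05, the smallest possible, adjusted p = 1e-05 for both). Where the motif lies among the windows was not determined. Of the 26 windows named swap, 12 were lower and 0 higher, the lowest at position 45 with -0.85 ± 0.83 (lower at all but 2 of 25 sites; permutation p = 5e-05, adjusted p = 0.004). Of the 28 windows named comp, 4 were lower, at positions 5, 10, 85 and 110, the lowest at position 10 with -0.58 ± 0.77. Whether comp and swap windows have the same length was not examined, so these counts do not compare the kinds of alteration. Of the swap windows, those at 15, 35, 70, 80 and 110 did not pass under at least 1 setting that kept all barcodes, and of the comp windows that at 5 did not pass with summed barcodes. Comp position 110 did not pass with a pseudocount of 0.5 (-0.36, permutation adjusted p = 0.0516), with no count minimum or by the median over sites. The count of comp windows rose to 8 with a pseudocount of 5, with 5 times the count minimum or with summed barcodes. Of the 26 windows in the ctrl form (ctrlswap), 0 passed, and 0 had an unadjusted p under 0.05. The ctrl form itself already had a mean activity of -1.41, against 0.25 for wt. With the first of 2 random subsets of the barcodes, 2 swap windows and 0 comp windows passed. Over barcodes, 17 of the 25 sites were more active in the native form and 1 less active. The largest effects were at sites 39 (3.18), 142 (3.00) and 100 (2.88), which also ranked among the first 5 in pool 1. The exception was site 509 (-1.01), also lower in pool 1.

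**Figure D2:**
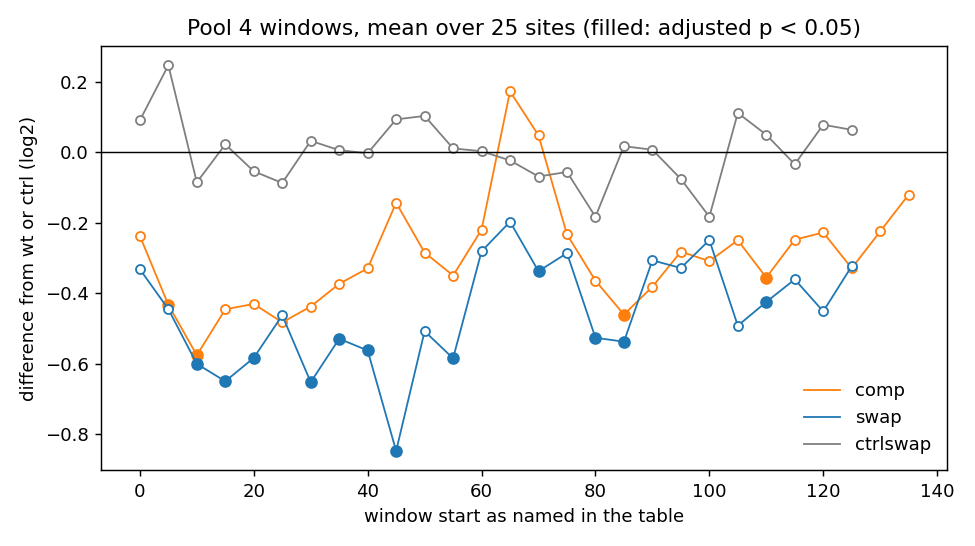
Mean log2 difference over 25 sites for each altered window of pool 4, by window start, against the wt element (comp, swap) or the ctrl element (ctrlswap). Filled points passed an adjusted p of 0.05, and the lowest, swap at 45, stands at -0.85.

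Pool 5 altered predicted motifs at 245 sites, those named ppar, pparg and rxr as well as motifs of other factors. Altering a named motif lowered activity more than altering control sequence. Named instances differed from wt by -0.82 ± 0.88 (n = 1598) and ctrl alterations by -0.33 ± 0.80 (n = 831), a difference of -0.49 (p = 1e-05 for each, the smallest possible). Against wt, 34 of 39 motif names were lower, and against their own ctrl alterations 19 of 37 were lower, with 0 higher in either and 0 higher at an unadjusted p under 0.05. The largest differences from ctrl were at jdp2 (-1.54, n = 8 instances, permutation adjusted p = 0.0264), atf3 (-1.25, n = 21, adjusted p = 0.000148), fos (-1.24, n = 17, adjusted p = 0.000123), dax1 (-1.19, n = 23, adjusted p = 0.00277) and jun (-1.03, n = 35, adjusted p = 0.000123). By medians, jdp2 (-1.02, permutation adjusted p = 0.146) and dax1 (-0.99, adjusted p = 0.0655) did not pass, nor did couptf, err1 and tr4. Of 6 names of AP-1, the FOS and JUN dimers, and related bZIP factors, 5 were lower, all but bach1, whose adjusted p was 0.0735. Both ATF names were lower. Families were not tested against each other. Of 14 nuclear receptor names 11 were lower, with a median of -0.63, among them ppar (-0.67, n = 102) and rar (-0.71, n = 88). Of the C/EBP and PAR bZIP names 1 of 4 was lower, cebp at -0.47, with a median of -0.52 over the 4. None of the 3 forkhead and 2 NFI names passed, with medians of 0.02 and -0.06. Alterations of a site share its wt element but were tested as if independent. Instances of several names overlap, and 586 elements in 293 groups shared their values, so names are not independent either. By size, hnf4_111 at site 73 ranked lowest with 1 RNA count, too few for a fold, followed by cebp_55 at site 49 (-4.05), and the largest rise nf1_31 at site 370 (2.75).

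Pool 6 inserted 39 motifs into 95 slots at 15 sites. Motifs of AP-1 and related factors, and those named ppar and rxr, raised activity above the mean of their slot. Of 39 motifs 14 were higher and 18 lower. Differences from a slot mean balance within the slot, so motifs far above it place others below it. The highest were bach1 (1.05 ± 0.63, higher in 93 of 95 slots), ap1 (0.89 ± 0.66, 86 slots), ppar (0.78 ± 0.46, 92 slots), rxr (0.78 ± 0.42, 94 slots), fra1 (0.62 ± 0.70) and jun (0.55 ± 0.56), each with permutation adjusted p = 1.5e-05. All 6 names of AP-1 and related bZIP factors were higher. The lowest were sna (-0.71 ± 0.45) and slug (-0.68 ± 0.48), motifs of the Snail family of repressors, each with permutation adjusted p = 1.5e-05. Nuclear receptor names divided, with 3 of 14 higher and 4 lower, the lowest err3 (-0.52). The name pparg, unlike ppar, did not pass against the slot mean (0.02 ± 0.32, permutation adjusted p = 0.522). Against wt, 6 motifs were higher, led by bach1 (0.79 ± 1.16) and ap1 (0.63 ± 1.13), and 25 lower. Among the lower was pparg (-0.23 ± 0.89, permutation adjusted p = 0.0178), which did not pass by means over sites (-0.18, adjusted p = 0.443). Slots of a site are not independent, and by means over the 15 sites 13 were higher and 17 lower than the slot mean, while 5 were higher and 12 lower than wt. Slots given another motif differed from wt by -0.26 ± 0.87 on average (permutation adjusted p = 0.00854) and slots given their own motif name by -0.15 ± 0.88 (adjusted p = 0.105; n = 95). By the median these were -0.040 (permutation adjusted p = 0.455) and -0.12 (adjusted p = 0.0282), so the calls changed places. By size, the largest rise was ap2_48_59_bach1 at site 240 (3.05) and the largest drop couptf_77_92_nr2f2 at site 223 (-4.76, 16 RNA counts).

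Motifs whose alteration lowered activity in pool 5 tended to give activity above the slot mean when inserted in pool 6. Across 36 motif names, which are not replicates, r was -0.461 (p = 0.00464; -0.507 without the 2 farthest) and rho -0.488 (p = 0.00286), a single relation computed after the data were seen. There were 9 names lower when altered and above the slot mean when inserted, of which 5 were also above wt, and 4 lower in both (cebp, atf3, hnf4 and tr4). By medians, tr4 did not pass in pool 5 (-0.31, permutation adjusted p = 0.197) nor hnf4 in pool 6 (-0.067, adjusted p = 0.0509). Of the 9 names, dax1 (-0.99, permutation adjusted p = 0.0655) and jdp2 (-1.02, adjusted p = 0.146) did not pass in pool 5 by medians. Related names, such as those of AP-1, count several times in the relation, while the permutations took all names as independent.

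**Figure D3:**
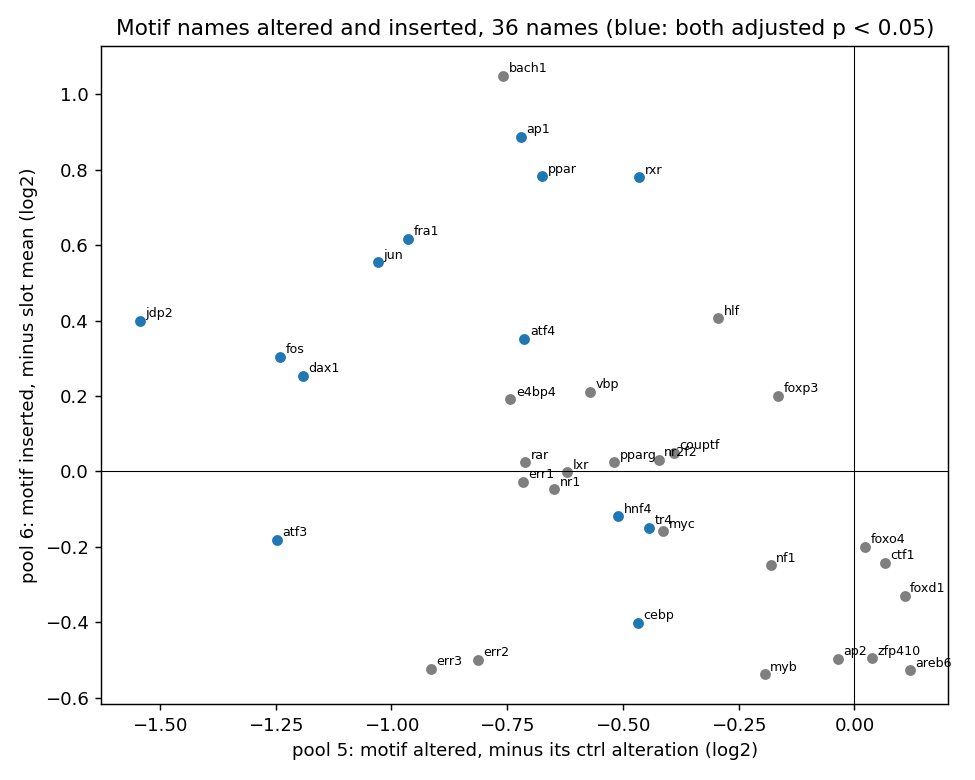
For 36 motif names, the log2 effect of altering the motif against its ctrl alteration (pool 5, x axis) and of inserting it against the slot mean (pool 6, y axis), with names in blue where both passed. The fos, jun, fra1, jdp2 and ap1 names lie at upper left, and bach1 highest at 1.05.

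Pool 7 placed arrays of 15 motifs, alone and in pairs, in 3 backgrounds on chromosomes 13, 15 and 9. A number in each name, 2, 4 or 6, was read here as the number of copies, and the last number was not interpreted. Most pairs with a ppar, bach1, fra1, jun or fos motif were more active than their background. Of 120 pairs 46 were higher, led by bach1/fra1 (2.37 ± 1.72, higher in 24 of 27 arrays, permutation adjusted p = 0.000133), bach1/bach1 (2.20 ± 1.28, 26 of 27, adjusted p = 0.000133) and ppar/jun (2.12 ± 1.92, 26 of 27, adjusted p = 0.0003). Of the 15 pairs with ppar 13 were higher, and of the 54 with fos, jun, fra1 or bach1 34 were higher and 1 lower (fos/myb, -1.39, permutation adjusted p = 0.0278). Of the 55 pairs with none of these motifs 3 were higher and 14 lower. Of 120 pairs 15 were lower, by the mean led by foxd1/myb (-2.37 ± 3.17, permutation adjusted p = 0.00129) and myb/myb (-2.10 ± 3.28, adjusted p = 0.00884). Medians were smaller, -0.91 for foxd1/myb and -1.42 for myb/myb, and by the median 6 of the 15 pairs remained, without myb/myb and fos/myb (permutation adjusted p = 0.058 and 0.373). Without the chromosome 13, 15 and 9 backgrounds in turn, 6, 9 and 8 pairs were lower. All 15 lower pairs had a mean difference below 0 in each of the 3 backgrounds, and 45 of the 46 higher pairs one above 0. These pairs were called on the same arrays. The arrays of a pair share 3 backgrounds, each measured as 1 element, and are not independent. With at least 2000 plasmid counts per element, 1 pair was lower. Of 3243 elements 178 had 0 RNA counts, 136 of them in the chromosome 15 background, whose median plasmid count was 982 against 3857 and 3994. The 10 lowest elements all had 0 RNA counts and are given no fold, and the highest was bach1_jun_4_1 in the chromosome 15 background (7.60).

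Activity rose with copy number, by 1.27 ± 2.89 from 2 to 6 copies (n = 1075; p = 1e-05, the smallest possible, adjusted p = 2e-05), and by 0.97, 2.12 and 0.73 in the chromosome 13, 15 and 9 backgrounds. In single-motif arrays 6 of 15 motifs passed, all rising. Single-motif arrays of fra1 (3.48), jun (3.13), myc (3.08) and ppar (1.48) rose in all 9 arrays (exact permutation p = 0.00391, adjusted p = 0.0146), and fos (2.87) and e4bp4 (1.24) in 8 of 9 (exact p = 0.00781, adjusted p = 0.0195). Their medians ranged from 0.88 (e4bp4) to 3.58 (fra1). Of the other 9 motifs, 5 were above 0 and 4 below, ap2 (-2.57), myb (-2.25), foxd1 (-1.75) and vbp (-0.29). Mixed arrays exceeded the mean of their 2 single-motif arrays by 0.11 ± 0.41 over 105 pairs (permutation p = 0.00567), which on a linear scale was -0.053. Each motif enters many of these pairs with the same single-motif arrays, so the pairs are not independent. Of these 105 pairs 0 passed alone, with 8 higher and 1 lower at an unadjusted p under 0.05, whereas on a linear scale 1 was called higher and 11 lower. The excess was 0.024 without the chromosome 9 background (permutation adjusted p = 0.668) and 0.020 with at least 2000 plasmid counts (adjusted p = 0.542).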

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

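Of the tests in this part, that of remaining binding was chosen after the result was seen, and that of plasmid counts was written before its value was computed.

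The effect of altering the motif differed between w and c sites, by a test of the difference itself. The difference was 0.57 for activity in pool 1 (p = 1e-05, the smallest the permutations can give), 0.19 for binding in pool 1 (p = 0.00098) and 0.42 for activity in pool 3 (p = 1e-05).

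Signal also appeared in rows of pool 5 that carry no element name. There were 101 such rows, with 3.00% of RNA and 4.90% of plasmid counts. Their median activity was -1.26, against -0.87 for named elements, and the highest was 3.47. They are not used in any comparison.

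Altered w elements of pool 1 stayed more active than altered c elements, by 0.30. A difference in plasmid counts between the classes would have shrunk the difference within 5 bins of the plasmid count, where it was 0.30 (95% bootstrap interval 0.25 to 0.35). PPARγ binding left at altered w elements would make binding and activity correlate across them, but rho was 0.00812 (interval -0.07 to 0.09, against 0.214 for native w elements). The first test argues against plasmid counts as the whole source. The second does not exclude binding, since noise in the ChIP values lowers any correlation and altered w elements were bound more than altered c elements by 0.11 (permutation adjusted p = 0.0334; by the median 0.090, adjusted p = 0.203), so binding left at altered w elements stays open. Each pair of w and c elements shared its 16-base motif sequence (750 of 750) within the same libraries, which points to sequence around the motif. Whether the altered bases were the same in both classes was not examined. Which surrounding sequence matters was not tested and stays open. Binding left at altered w elements could be a way for that sequence to act, and is not an alternative to it.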

How the results depend on the processing

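No paired analysis was possible between replicate libraries because each pool had 1 library of each type, so pairing was only by site. Among the values that answer a comparison, 428 kept their direction and side of the threshold, or their count within 1.5 times, under settings that moved the values behind them, and 5 lost significance, 1 gained it, 3 changed sign and 40 counts moved further. A further 106 were left untouched by their setting and test nothing, among them all 58 under median centring, which cancels in differences within a pool. For single motifs, windows, pairs and sites, 889 kept and 169 lost their call, none with a change of sign, while 545 untouched ones kept it and 1 lost it only because the adjusted family changed. The background, 500-count, 2000-count, shared-value and per-site settings were chosen after seeing the data. With a pseudocount of 0.5, all values that answer a comparison kept their direction and side of the threshold, or their count within 1.5 times. Among single windows, pairs and sites, 6 lost their call at that setting. Not run were replicate blocks, leaving out replicates and count models, since no library had a replicate, and another affinity score and a read minimum for the barcode maps, which the tables do not give. Those single elements whose plasmid counts fell below the stricter minimum gave no value at that setting. Medians of single-motif arrays were not tested, since sign flips of a median over 9 arrays cannot pass. Where no cause is named, the cause was not tested.

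In 2 random subsets of the barcodes, pool 1 w sites went from 237 higher and 4 lower to 0 and 0 in both subsets. The c sites went from 10 and 2 to 0 and 0. Fewer barcodes raise the smallest p an exact test can reach, but whether this alone removed the calls was not tested. Pool 3 w sites went from 262 and 17 to 102 and 6 in the first subset and 160 and 7 in the second, and c sites from 9 higher to 0 in both. Pool 4 sites higher in the native form went from 17 to 11 and 9, those lower from 1 to 0 in the second subset, and windows lower in the first subset from 12 to 2 (swap) and from 4 to 0 (comp). With 5 times the count minimum, sites lower in the native form went from 4 to 2 and from 2 to 1 in pool 1 (w, c) and from 17 to 10 in pool 3, comp windows from 4 to 8, and mixed pairs of pool 7 above their single-motif arrays from 0 to 1. With no minimum, c sites of pool 1 lower in the native form went from 2 to 1. A pseudocount of 5 gave 8 comp windows. Summed barcodes gave 8 comp windows, 1 ctrlswap window higher and a c-site effect of 0.051 in pool 3 (permutation adjusted p = 0.0704). By the median over sites, altered w minus c binding was 0.090 (permutation adjusted p = 0.203), slots of pool 6 given another motif -0.040 against wt (adjusted p = 0.455; by the mean -0.26, adjusted p = 0.00854) and slots given their own motif name -0.12 (adjusted p = 0.0282; by the mean -0.15, adjusted p = 0.105). The same setting gave 6 lower pairs in pool 7 and 2 mixed pairs higher. The near-zero rho of native w and c activity, -0.00544, was 0.00738 with at least 5 barcodes and 0.0158 in the second subset. On a linear scale the excess of mixed arrays was -0.053, with 1 pair higher and 11 lower. Pairs of pool 7 below their background went from 15 to 6, 9 and 8 without the chromosome 13, 15 and 9 backgrounds, and to 6 and 1 with at least 500 and 2000 plasmid counts, settings that test fewer elements and gave 2 mixed pairs higher each. The excess of mixed arrays was 0.024 without the chromosome 9 background (permutation adjusted p = 0.668) and 0.020 with at least 2000 counts (adjusted p = 0.542). By means per site, 12 motifs of pool 6 were lower than wt in place of 25.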

Other observations

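All tests of explanations in this part were chosen after the result was seen, as were the comparisons across pools.

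The same 25 sites were measured in pools 1, 2 and 4, in separate libraries. Across sites, native activity in pools 1 and 2 correlated with r = 0.974 (0.966 without the 2 farthest; rho = 0.978), in pools 1 and 4 with r = 0.897 (0.867; rho = 0.918) and in pools 2 and 4 with r = 0.928 (0.906; rho = 0.942). The difference between altered and native forms correlated with r = 0.926 (0.867; rho = 0.914), 0.830 (0.739; rho = 0.815) and 0.804 (0.694; rho = 0.848) for the same pairs of pools. Native activity of 11 sites in pools 5 and 6 correlated with r = 0.965 (0.923; rho = 0.936). Each r had p = 1e-05 and each rho p = 1e-05, the smallest the permutations can give, apart from p = 0.00013 for rho in pools 5 and 6. Adjusted over the 7 relations, p was 1e-05 for r and 1.17e-05 for rho, or 0.00013 for the last. Across sites these are not replicates of the cultures.

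The column headed IP in the pool 2 ChIP table matched values rebuilt from the input and the pool 2 reporter counts in 595 of 595 cases. Agreement of separate assays would leave noise at least as large as that between random subsets of the barcodes of 1 assay, 0.31 on the log2 scale, but the median difference was 0.00198. The values therefore suggest a column computed from reporter data rather than ChIP reads, with the reservation that the formula was found by a search over 112 combinations on the same values. How this arose cannot be learned from the table. No biological explanation was tested.

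The 15 motif pairs of pool 7 below their background may reflect low plasmid counts. Among elements with at least 2000 plasmid counts their mean difference was -0.36 (interval -0.51 to -0.22) against -1.47 over all their elements, and their median difference was -0.27 (-0.44 to -0.09) against -0.71. The share left was 0.246 by the mean (0.147 to 0.350) and 0.381 by the median (0.162 to 0.622), and neither decides by the bounds set. The minimum of 2000 and both bounds were chosen after effects by count had been seen, and an earlier comparison of the high-count median with the overall mean, which favoured the explanation, was dropped because it mixed statistics. The 46 higher pairs kept a mean of 1.40 and a median of 1.34 there, against 1.41 and 1.44, which argues against low counts as their source, and no biological explanation was tested.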
